A study of Mus musculus with 6 samples.

How the data were processed

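RNA from whole adrenal glands of clock-deficient Per2 and Cry1 double mutant male mice was hybridised to 1 array per sample, with 3 arrays from 46 h and 3 from 54 h after lights off. Per the labels' protocols, total RNA was extracted with a column kit for small samples and labelled with biotin. The values are those the authors deposited in 1 table for the whole series: 1 intensity per probe set and array, on a linear scale, for an Affymetrix mouse array. The method that summarised probes into probe sets, the background correction and the normalization were not given in the sources used here. The deposited intensity values already shared a scale, since the array medians after filtering differed by 0.0728 on the log2 scale, within the limit of 0.1 set for using values without further normalization. Signals that approach the top of the scale, 17879 units, understate differences, and signals near 0 are dominated by background.

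The table held 45001 probe sets. Left out were 64 Affymetrix controls, 1 probe set with no value on any array, and 1 with a damaged value of 1.32e+11 on 54h replicate 1 against 41.1 to 80.1 on the others, which left 44935. Probe sets were named through the platform's annotation: 34848 named exactly 1 gene, 928 several and 9159 none, and no gene was named from a probe set with several. Symbols were looked up through the gene ID in a RefSeq table of assembly GRCm38.p6, which held the gene ID of 34644 of those probe sets and changed 0 symbols. No coordinates are given because the deposited table names no genome build.

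Values were transformed as log2(intensity + 16), so fold changes are on that scale and understate the change of dim probe sets. Probe sets were kept if their mean over the 6 arrays was above the 40th percentile, which left 26961. Arrays of 54 h were compared with those of 46 h in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. A test by exact permutation of 3 against 3 arrays cannot give a p under 0.1, so single values were tested only within the model over all probe sets. The labels give no animal for each array, so the p-values measure the spread between these samples, which may be technical in part. Python 3.11.15 and matplotlib 3.10.9 served for tables and plots.

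Gene lists were tested with limma's camera with a preset correlation of 0.01, each gene represented by its probe set with the highest mean, for lists with at least 5 genes measured, and adjusted over 23 lists. Of 501 genes on 26 lists, 447 had a probe set. The lists were core clock, clock output, steroidogenesis, cholesterol synthesis, glucocorticoid-responsive, immediate early and cAMP-induced, heat shock, temperature-responsive RNA-binding, cell cycle, interferon response, lipid droplet and fatty acid metabolism, oxidative stress, oxidative phosphorylation, unfolded protein response and ribosomal proteins. Markers of tissue parts and neighbours covered the medulla, zona glomerulosa, X-zone, capsule and stroma, adipose tissue, blood cells, endothelium, immune cells, kidney, liver and skeletal muscle. Some genes are on 2 lists, such as Dusp1. Single genes were also adjusted over the measured genes of their list alone. That adjustment does not correct for the number of lists, and some lists held few measured genes. Camera was repeated with an estimated correlation, and fry was run on the same lists, for change in 1 direction on balance and in either direction.

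The genes named were fixed by a rule: Per2 and Cry1; every measured gene of both clock lists; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, filled up by the smallest unadjusted p where fewer passed; and up to 4 genes with the smallest p in each other list, with up to 2 well-known members. The comparison, the filter, the offset, the lists, this rule and all alternatives but 1 were chosen before the data were examined; the exception, the liver signal as a covariate, is named in the closing part. Alternatives were quantile normalization, centring on array medians, no filter or one at the 60th percentile, offsets of 1 and 64, eBayes without a trend or robust, array weights, the replicate letter as a block, other thresholds, other list tests, the mean over the probe sets of a gene, and leaving out each array in turn.

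The procedure was tested on simulated data for this comparison, with 26961 probe sets at the means and spreads seen here, 200 of them changed, in 20 data sets. It recovered 4.5% of probe sets changed 1.25-fold, 33.2% of those changed 1.5-fold, 78% of those changed 2-fold and 94.4% of those changed 3-fold, and 4.93% of its calls were false. A list shifted by 0.3 on the log2 scale was called in all 20 data sets, with 0.1 other lists called on average. The simulated noise was independent between probe sets, whereas genes of some lists varied together here (estimated correlation 0.703 for cholesterol synthesis). The simulated rates of false calls, above all for lists, may therefore not hold for these data. The median SE of a log2 change in the data was 0.12.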

Results

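The series measured RNA in whole adrenal glands of male mice, 3 months old, that carry the Per2Brdm1 mutation and lack Cry1 on a mixed C57BL6 and 129Sv background. Per2 and Cry1 encode repressors of the circadian clock, and the labels describe the double mutants as having no working clock. The mice were kept in a light-dark cycle for 2 weeks and then in constant darkness, and glands were taken 46 h or 54 h after lights off. Each time point had 3 arrays, named replicates 1, B and C. According to the labels the set served to find adrenal genes that the clock regulates whether or not they are rhythmic; wild-type glands were not analysed here. The only comparison among these arrays was therefore between 2 time points 8 h apart, and it asked which transcripts differed between them in glands without a working clock. The labels give no other factor. Any difference in collection, dissection or labelling between the time points therefore cannot be told apart from time. The median intensity per array was 204 to 217 units and the highest value was 17879. The number of arrays limits the precision.

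Sbsn, which encodes the secreted protein suprabasin, fell 2.24-fold between 46 h and 54 h, from 6915 ± 384 to 3083 ± 205 intensity units (SD, n = 3 each; log2 change -1.16 ± 0.06 SE, limma adjusted p = 0.000247). The other 2 Sbsn probe sets also passed, with log2 changes of -1.24 and -1.37. Ednrb, the endothelin receptor type B, rose 1.58-fold from 1866 ± 87.2 to 2957 ± 39.7 (SD, n = 3 each; limma adjusted p = 0.0168). Genes of cholesterol synthesis (Hsd17b7 and Idi1), genes known for expression in liver (Cyp3a11 and Serpina1b) and the beta-globin gene Hbb-b2 were among those that rose. The regulator of germline DNA methylation Dnmt3l, the homeobox gene Hhex and the cytochrome b5 gene Cyb5a, whose product supports P450 enzymes, were among those that fell.

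In all, 31 of 26961 probe sets passed limma at an adjusted p of 0.05, 16 higher and 15 lower at 54 h. Of these, 28 named exactly 1 gene and together named 23 genes, 14 higher and 9 lower. With each gene read from its brightest probe set, 15 genes passed. Hsd17b7 rose 2.25-fold, Cyp3a11 2.22-fold, Serpina1b 2.15-fold, Hbb-b2 2.06-fold, 4932437C15Rik 1.60-fold, Idi1 1.45-fold and Psat1, an enzyme of serine synthesis, 1.24-fold. The limma adjusted p of these 7 genes lay between 0.0288 and 0.0499. Dnmt3l fell 1.97-fold, Erdr1 1.88-fold, Prxl2b 1.65-fold, the snoRNA host transcript Zfas1 1.46-fold, Hhex 1.42-fold and Cyb5a 1.27-fold, with limma adjusted p between 0.0288 and 0.0419. Next in order but not past the test were Dsg2, a desmosomal cadherin, with a log2 change of 0.82 ± 0.12 SE, and Eprs, the glutamyl-prolyl-tRNA synthetase, with 0.62 ± 0.09 SE. On the other side stood the galactokinase gene Galk2 with -0.54 ± 0.08 SE, the glutathione transferase gene Mgst2 with -1.01 ± 0.15 SE and the snoRNA host Snhg1 with -0.52 ± 0.08 SE. The limma adjusted p was 0.0501 for Galk2 and 0.0539 for the other 4. Probe sets of a gene did not always move together. Other Ednrb probe sets had log2 changes of 0.18 and -0.06, the other Erdr1 probe set had 0.02, the other Hbb-b2 probe set had 0.22, and 1 of the 4 for Hsd17b7 had -0.05, none past the test. Hbb-b2 and Serpina1b belong to families of near-identical genes, so which member their probe sets read is uncertain.

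**Figure D1:**
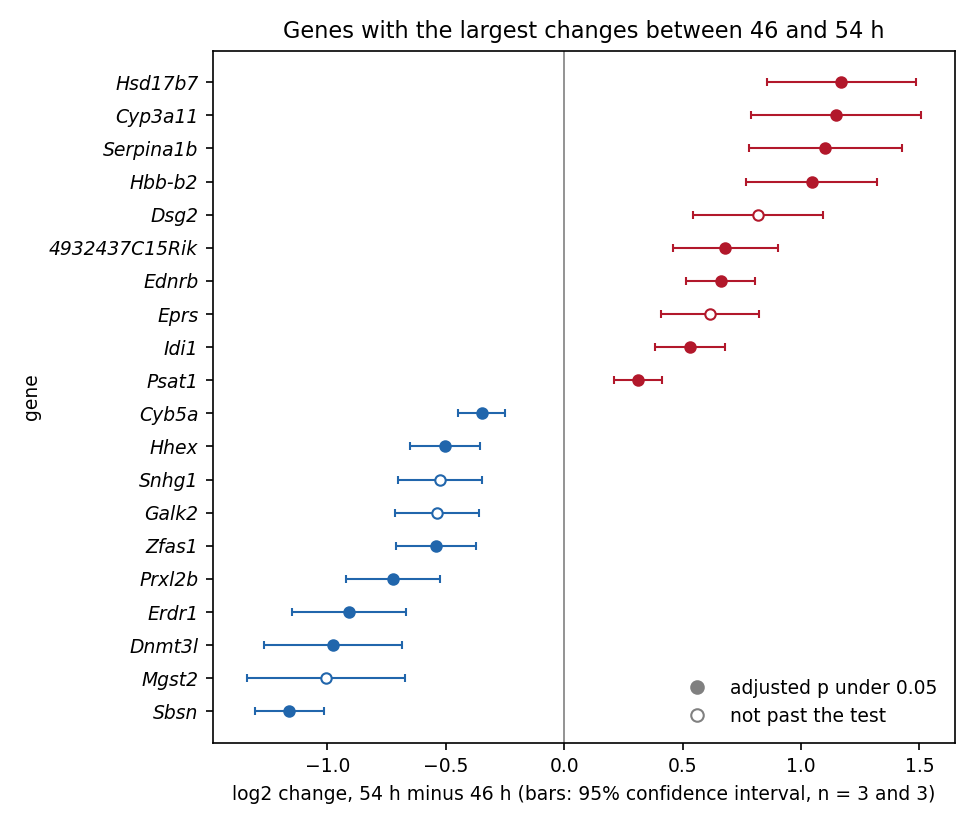
Log2 change between 46 h and 54 h (54 h minus 46 h, horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall, or the smallest p where fewer passed; points are estimates from 3 arrays per time point and bars are 95% confidence intervals. Filled points passed limma at an adjusted p of 0.05; Sbsn lies lowest at -1.16 and Hsd17b7 highest at 1.17.

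At an unadjusted p of 0.05 limma gave 2719 of 26961 probe sets, 1170 higher and 1549 lower, where 1348 would be reached by chance. Counts of list genes at that level, given below, are to be read against this share. The excess of lower probe sets depended on the scaling: with arrays centred on their medians 1152 were higher and 1022 lower, and with quantile normalization 1590 and 1529. The values of the time points did not overlap for 4188 probe sets, or 15.5%, against 10% by chance. All 31 that passed were among them, which follows largely from their selection by a small p on the same arrays and adds no support. The count of 31 became 2 without 46h replicate 1, 18 without 46h replicate B, 66 without 54h replicate 1, 61 without 54h replicate B, 2 without 54h replicate C, and 30, of which 7 were lower, without 46h replicate C. It was 3 without an intensity trend in the variance, 61 with a robust fit and 3466 with array weights. Those weights rest mostly on 46h replicate 1 and 54h replicate C, so 3466 does not measure how many probe sets changed. Sbsn passed in all 6 fits that left out an array, and the other 14 genes named above as past the test passed in 0 to 4 of them.

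The clock genes themselves showed no change past the test. Of the 15 core clock genes measured, 0 passed limma over all probe sets, 0 when adjusted over the list alone, and 0 reached an unadjusted p of 0.05. Per2 stood at 1323 ± 182 units at 46 h and 1211 ± 362 at 54 h (SD, n = 3 each), a log2 change of -0.16 ± 0.20 SE. The Cry1 probe set read 107 ± 19.6 and 77.2 ± 20.3 units (SD, n = 3 each), under the filter on low values. Whether these probe sets lie in the mutated parts of the genes was not given, so the levels do not check the genotype. Among activators, the log2 change was 0.11 for Arntl, 0.01 for Clock and 0.12 for Rora. Among repressors it was 0.25 for Per1, 0.08 for Per3, -0.17 for Cry2, 0.18 for Nr1d1, -0.04 for Nr1d2, 0.15 for Ciart, -0.03 for Bhlhe40 and -0.02 for Bhlhe41. The kinases Csnk1d and Csnk1e had -0.05 and -0.20, and Timeless had -0.14. The 95% confidence intervals of all 15 genes excluded a 2-fold change and those of 13 excluded a 1.5-fold change. The outermost bounds were -0.61 for Per2 and 0.68 for Per1. On 54h replicates 1, B and C Per2 read 829, 1550 and 1253 units and Per1 458, 833 and 701, so 1 array offset the others. For both, 54h replicate 1 lay below every 46 h array. By contrast, Nr1d1 and Cry2 read higher on 54h replicate 1 (706 and 954 units) than on B and C. Npas2, like Cry1, lay under the filter. As a list, the core clock did not pass (limma camera adjusted p = 0.585).

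**Figure D2:**
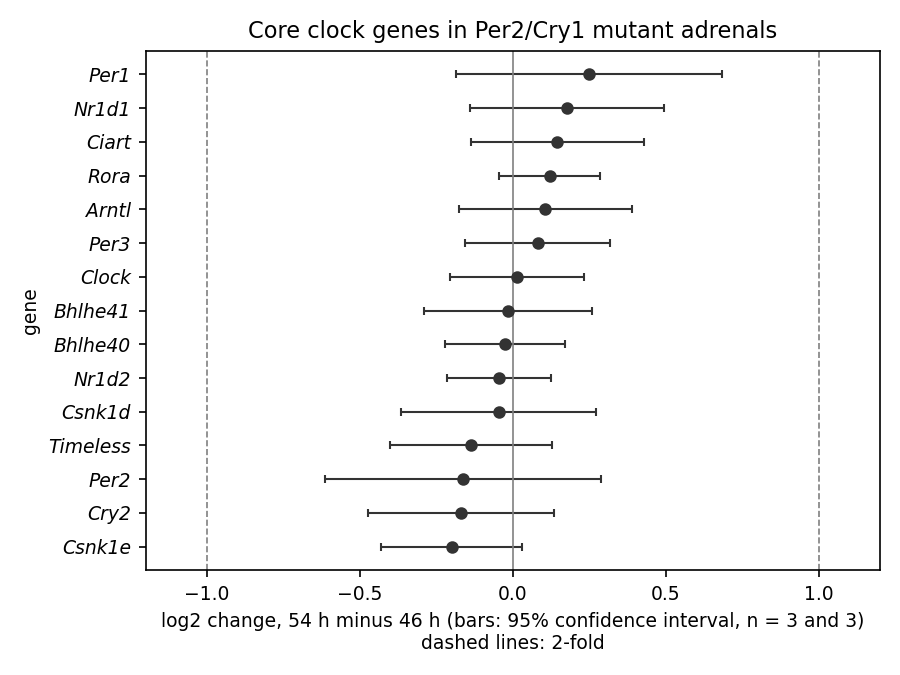
Log2 change between 46 h and 54 h (54 h minus 46 h, horizontal axis) of the 15 core clock genes measured; points are estimates from 3 arrays per time point, bars are 95% confidence intervals and dashed lines mark a 2-fold change. Every interval includes 0 and lies inside the 2-fold lines, the widest being that of Per2.

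Of 13 clock output genes measured, 0 passed limma over all probe sets and 1 passed, lower, when adjusted over the list alone; 1 reached an unadjusted p of 0.05. That gene was Tfrc, the transferrin receptor, with a log2 change of -0.49 ± 0.12 SE (limma adjusted p = 0.199). The PAR bZIP factors Dbp, Tef and Hlf had log2 changes of 0.06, -0.05 and -0.17. Nfil3, their antagonist, had the widest spread, at 373 ± 82.3 and 754 ± 483 units (SD, n = 3 each), a log2 change of 0.78 ± 0.42 SE. It read 291, 1255 and 716 units on 54h replicates 1, B and C. The rest had 0.37 (Pdk4), 0.17 (Usp2), 0.17 (Noct), 0.15 (Avp), 0.03 (Tspan4), -0.02 (Ppard) and -0.13 (Wee1). The list did not pass (limma camera adjusted p = 0.585).

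Immediate early and cAMP-induced genes, which respond within minutes to hours to stimuli such as ACTH or stress, rose as a list (median log2 change 0.34, limma camera adjusted p = 6.42e-09), with 18 of 21 members higher at 54 h. With an estimated correlation between genes the list did not pass (adjusted p = 0.616), nor did it with the liver signal as a covariate, chosen after the data were seen (median 0.07, limma camera adjusted p = 0.753). No member passed limma over all probe sets (0 of 21, with 10 at an unadjusted p of 0.05, all higher), and 5 passed when adjusted over the list alone. Dusp1, a MAP kinase phosphatase, had a log2 change of 0.68 ± 0.10 SE, Fos 1.62 ± 0.32, Junb 1.55 ± 0.31, Crem 1.02 ± 0.22 and Rgs2 0.30 ± 0.08 (limma adjusted p between 0.0539 and 0.224); Nr4a1 had 0.50 ± 0.19 and Egr1 0.55 ± 0.37. The list mean lay 0.76 and 0.54 above the 46 h mean on 54h replicates B and C but 0.13 on 54h replicate 1. Its median change was 0.55 without 54h replicate 1 and 0.18 without 54h replicate B. Heat shock and chaperone genes did not pass as a list (limma camera adjusted p = 0.585), nor did any of the 20 members (0, and 0 adjusted over the list alone; 3 higher and 1 lower at an unadjusted p of 0.05 in limma). Without 54h replicate 1 the list passed as higher (median log2 change 0.03, limma camera adjusted p = 0.0121). Inducible Hspa1a had a log2 change of 1.01 ± 0.41 SE, Hspa1b 0.67 ± 0.28, Cryab 0.60 ± 0.18 and Ahsa1, a co-chaperone, -0.17 ± 0.06. On 54h replicate 1 Hspa1a and Hspa1b read 1028 and 3747 units, under their 46 h means of 1165 and 4099; their log2 changes were 1.60 and 1.07 without that array, where both passed limma, and 0.60 and 0.41 without 54h replicate B, where neither did. Of 19 glucocorticoid-responsive genes 0 passed over all probe sets and 2 passed adjusted over the list alone, Dusp1 higher and the metallothionein gene Mt1 lower (-0.27 ± 0.05). In that list limma gave 3 higher and 1 lower at an unadjusted p of 0.05, and the list did not pass (limma camera adjusted p = 0.338).

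Cholesterol synthesis genes rose as a list (median log2 change 0.27, limma camera adjusted p = 8.92e-09), with 18 of 19 members higher at 54 h. With an estimated correlation the list did not pass (adjusted p = 0.680). With the liver signal as a covariate, chosen after the data were seen, the median reversed to -0.15 and did not pass (limma camera adjusted p = 0.861). Over all probe sets 2 members passed limma, Hsd17b7 and Idi1, and adjusted over the list alone 6 passed, all higher. Among them Pmvk, the phosphomevalonate kinase, had a log2 change of 0.47 ± 0.12 SE, the lanosterol demethylase Cyp51 0.55 ± 0.14, Nsdhl 0.33 ± 0.10 and Insig1, which retains the SREBP pathway in the endoplasmic reticulum, 0.40 ± 0.13. As with the immediate early genes, the list mean stood higher on 54h replicates B and C, by 0.53 and 0.37, than on 54h replicate 1, by 0.03. Its median change was 0.15 without 54h replicate B. Liver genes were also higher on 54h replicates B and C (0.91 and 0.62 above the 46 h mean) than on 54h replicate 1 (0.40), the order of both lists. The steroidogenic genes that use cholesterol did not pass as a list (median log2 change -0.03, limma camera adjusted p = 0.941), and 0 of 17 passed limma over all probe sets or adjusted over the list alone, with 1, higher, at an unadjusted p of 0.05. Star had a log2 change of -0.05 ± 0.03 SE, Cyp11a1 -0.06 ± 0.03, Cyp11b1 -0.06 ± 0.04, the ACTH receptor Mc2r 0.00 ± 0.05 on 8195 and 8191 units, and Stard4, a sterol carrier, 0.42 ± 0.17. The mean of 7 of the 17 exceeded 14000 units, near the top of the scale, where differences are compressed.

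Lipid droplet and fatty acid genes went both ways. With each gene read from its brightest probe set, 0 of 20 measured passed limma over all probe sets. A dimmer probe set of Scd1 passed as higher (0.79 ± 0.11 SE, limma adjusted p = 0.0404), while its brightest had 0.06. At an unadjusted p of 0.05 in limma 5 genes were higher and 3 lower, and adjusted over the list alone 3 passed as higher and 2 as lower. The 3 higher were fatty acid synthesis genes, Acaca with a log2 change of 0.39 ± 0.07 SE, Elovl6 with 0.30 ± 0.08 and Fasn with 0.20 ± 0.05. The 2 lower were fatty acid oxidation genes, Cpt1a with -0.30 ± 0.05 and Acadm with -0.21 ± 0.05. This division by function was drawn after the values were seen and was not tested. The list did not pass (limma camera adjusted p = 0.585).

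Liver genes rose as a list and had the largest median log2 change of the lists that passed, 0.64 (limma camera adjusted p = 6.42e-09). With an estimated correlation the list did not pass (adjusted p = 0.616). Of 11 members, each read from its brightest probe set, 9 were higher at 54 h, 1 passed limma over all probe sets (Serpina1b), and 8 passed adjusted over the list alone. A dimmer Ttr probe set also passed over all probe sets (1.29 ± 0.19 SE, limma adjusted p = 0.0495). Apolipoprotein Apoa1 went from 198 ± 56.1 to 539 ± 154 units and albumin, Alb, from 2177 ± 558 to 4286 ± 958 (SD, n = 3 each). Their log2 changes were 1.38 ± 0.24 SE and 0.98 ± 0.20 SE, that of the thyroxine carrier Ttr 1.11 ± 0.18 SE and that of Apoa2 0.77 ± 0.22 SE. The list mean was 0.40, 0.91 and 0.62 above the 46 h mean on 54h replicates 1, B and C, and 0.15, -0.27 and 0.12 on the 46 h arrays. Among markers of other neighbouring tissues, adipose genes passed as a list (median log2 change 0.10, limma camera adjusted p = 0.0323; adjusted p = 0.882 with an estimated correlation). Of its 11 genes 0 passed limma over all probe sets, 1 (Cidea) passed adjusted over the list alone, and 3, all higher, reached an unadjusted p of 0.05. Cidea, a lipid droplet protein of brown fat, had a log2 change of 0.67 ± 0.17 SE, Ucp1 0.56 ± 0.22 and leptin, Lep, 0.59 ± 0.19, against -0.11 ± 0.11 for Adipoq. The adipose list did not pass without 46h replicate B, 46h replicate C or 54h replicate 1, with medians of 0.07, 0.10 and -0.02. Over all 6 fits that left out an array its median ran from -0.02 to 0.25. It passed in 9 of 18 alternatives, these fits included. Kidney genes did not pass (7 measured, limma camera adjusted p = 0.585), with 0 past limma by either adjustment or at an unadjusted p of 0.05; Kap had 0.08 ± 0.11 and Cyp2e1, also a liver gene, -0.28 ± 0.13. Skeletal muscle genes did not pass either (6 measured, limma camera adjusted p = 0.124), with 0 past limma over all probe sets, 2 at an unadjusted p of 0.05 and 2 adjusted over the list alone, Eno3 (0.50 ± 0.09) and Myl1 (0.40 ± 0.13). Of 4 erythroid genes, too few for a list test, Hbb-b2 passed, 2 passed adjusted over the list alone (Hbb-b2 and Alas2, 0.54 ± 0.17), and the alpha-globin gene Hba-a1 had -0.30 ± 0.30.

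**Figure D3:**
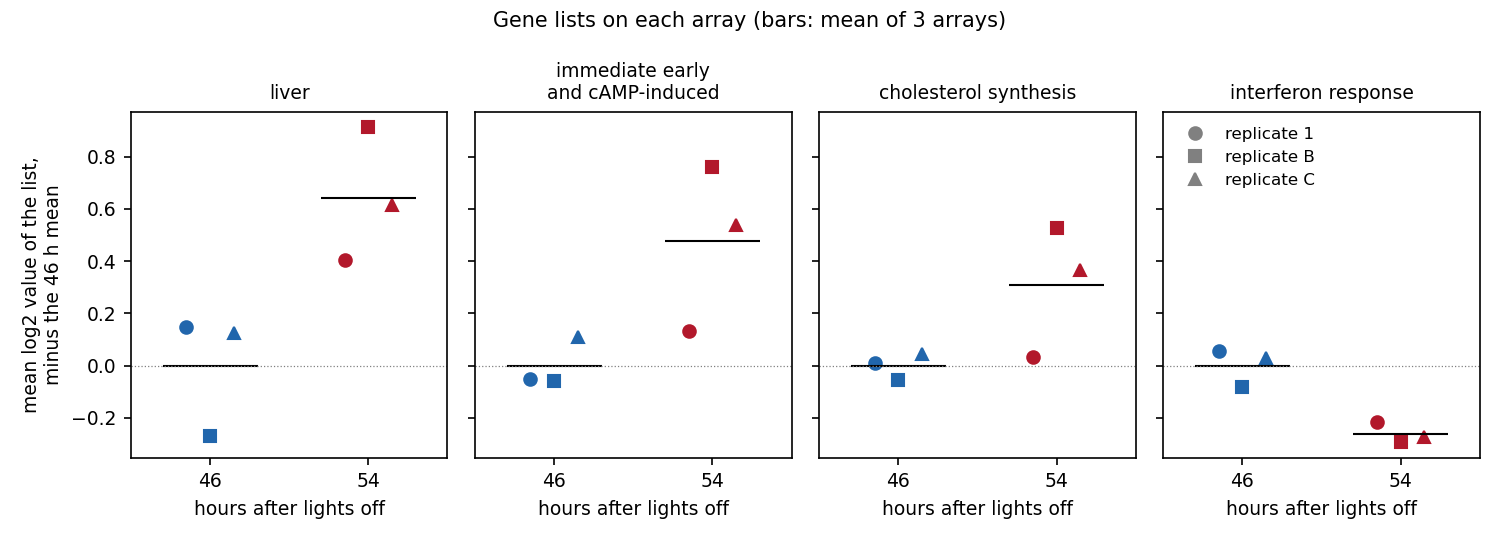
Mean log2 value over the measured genes of 4 lists on each array, minus the mean of the 46 h arrays (vertical axis), at 46 h and 54 h after lights off (horizontal axis); each point is 1 array, its shape the replicate, and lines are means of 3 arrays. The interferon list is lower on all 3 arrays at 54 h (-0.21, -0.29 and -0.27), while the immediate early and cholesterol synthesis lists on 54h replicate 1 (0.13 and 0.03) lie near the 46 h arrays.

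Interferon response genes fell as a list (median log2 change -0.21, limma camera adjusted p = 2.31e-07), with 20 of 21 members lower at 54 h. With an estimated correlation the list did not pass (adjusted p = 0.433, unadjusted p = 0.0188), nor did it with the liver covariate (median -0.34, limma camera adjusted p = 0.0565). No member passed limma over all probe sets (0, with 8 at an unadjusted p of 0.05), and 8 passed adjusted over the list alone, all lower. The deubiquitinase Usp18 went from 373 ± 52.7 to 220 ± 8.60 units (SD, n = 3 each), a log2 change of -0.71 ± 0.13 SE, the transcription factor Irf7 had -0.64 ± 0.13, Ifit3 -0.42 ± 0.10 and Bst2, a tethering factor for viruses, -0.55 ± 0.13. Immune cell markers were lower as a list (median log2 change -0.10, limma camera adjusted p = 0.0323; adjusted p = 0.882 with an estimated correlation), with 0 of 20 past limma over all probe sets, 7 lower at an unadjusted p of 0.05 and 4 adjusted over the list alone. These were Lyz2 (-0.37 ± 0.06), Lyz1 (-0.23 ± 0.05), C1qc (-0.38 ± 0.10) and Cd74 (-0.14 ± 0.04). Lyz1 and Lyz2 are closely related genes, and whether their probe sets tell them apart was not tested. The immune list did not pass without 46h replicate 1, 46h replicate C or 54h replicate B, with medians of -0.10, -0.09 and -0.10.

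Chromaffin cell genes of the adrenal medulla were lower as a list, by little (median log2 change -0.10, limma camera adjusted p = 0.0208; adjusted p = 0.882 with an estimated correlation). Of 23 genes 19 were lower, 0 passed limma over all probe sets or adjusted over the list alone, and 7, all lower, reached an unadjusted p of 0.05. The granule proteins Scg2 and Scg5 had log2 changes of -0.13 ± 0.04 SE and -0.28 ± 0.09 SE, Pcsk1n -0.25 ± 0.07 and Hand2 -0.18 ± 0.06, against -0.05 ± 0.04 for Th and -0.13 ± 0.13 for Pnmt, enzymes of catecholamine synthesis. The list did not pass without 46h replicate 1, 46h replicate C, 54h replicate B or 54h replicate C, with medians of -0.09, -0.07, -0.11 and -0.07. Genes of the capsule and stroma (16 measured), the endothelium (15) and the zona glomerulosa (11) did not pass as lists, with camera adjusted p of 0.269, 0.480 and 0.903; without 54h replicate 1 the stromal list passed as lower (median log2 change -0.10, limma camera adjusted p = 0.00714). None of their genes passed limma over all probe sets (0 in each; 4, 3 and 2 at an unadjusted p of 0.05). Adjusted over the list alone, 0 stromal genes passed, 1 endothelial gene, the VEGF receptor Kdr (-0.23 ± 0.05), and 1 glomerulosa gene, Vsnl1 (0.30 ± 0.06). Col6a1 had -0.17 ± 0.05, Col3a1 -0.44 ± 0.18, Wnt4 -0.30 ± 0.13 and the aldosterone synthase gene Cyp11b2 -0.07 ± 0.07. Of the X-zone list only 2 genes were measured. Akr1c18, Pik3c2g and Spink1 lay under the filter, at 84.0, 10.9 and 12.7 units at 46 h. Abcb1b, which read 11520 units at 46 h, had -0.37 ± 0.07 and passed adjusted over those 2 genes alone (limma adjusted p = 0.0922). With the other markers this low, its change cannot be assigned to that zone.

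The other lists did not pass camera. They were cell cycle (23 measured, limma camera adjusted p = 0.903), oxidative stress and NRF2 (16, 0.503), oxidative phosphorylation (36, 0.490), the unfolded protein response (21, 0.269) and cytosolic ribosomal proteins (25, 0.317). Over all probe sets 0 of their genes passed limma, with 6, 3, 9, 3 and 1 at an unadjusted p of 0.05, and adjusted over the list alone 1 gene passed, the sulfiredoxin gene Srxn1 (0.54 ± 0.12). Within the cell cycle list, the helicase genes Mcm2 and Mcm4 had log2 changes of 0.29 ± 0.10 SE and 0.30 ± 0.10 SE, whereas Rrm2 had -0.46 ± 0.12 SE and Top2a -0.35 ± 0.15 SE. Among the rest, Asns, the asparagine synthetase, had 0.43 ± 0.13 SE, Cox5a 0.15 ± 0.04 SE and Rps6 0.36 ± 0.12 SE. Of 4 temperature-responsive RNA-binding genes, too few for a list test, 0 passed over all probe sets, 2 reached an unadjusted p of 0.05 in limma and 2 passed adjusted over the list alone, Srsf5 (-0.45 ± 0.13) and Cirbp (0.33 ± 0.12). The sign of the median, the mean and the test differed for some lists that did not pass, among them core clock, zona glomerulosa and cell cycle. In all 23 lists were tested, 4 passed as higher and 3 as lower with the preset correlation of 0.01, and 0 passed with an estimated correlation (1 at an unadjusted p of 0.05) or with fry for change in 1 direction on balance (3 at an unadjusted p of 0.05). With the liver covariate 0 of the 22 other lists passed camera (5 at an unadjusted p of 0.05). Fry for change in either direction, which does not compare a list with other genes, passed 12 of the 23, including 7 that camera did not pass: lipid (adjusted p = 5.91e-05), skeletal muscle, NRF2, cell cycle, zona glomerulosa, oxidative phosphorylation and glucocorticoid-responsive genes (adjusted p = 0.0331).

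Of the control probe sets, those for 18S ribosomal RNA separated the time points. The 18S ribosomal RNA control at the 3′ end read 1154, 1143 and 1350 units at 46 h and 2395, 1526 and 1751 at 54 h, and that at the 5′ end read 157, 175 and 199 against 584, 227 and 231, so 54h replicate 1 was highest. The ratio of the 3′ to the 5′ actin control, a measure of RNA integrity, was 1.46 to 1.55 at 46 h and 1.48 to 1.57 at 54 h, and that for Gapdh 0.968 to 1.049 and 0.915 to 1.003. The hybridisation controls bioB and creX read 160 to 227 and 6950 to 8175 units at 46 h and 152 to 195 and 7686 to 8215 at 54 h, so these ranges overlapped.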

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

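The liver signal as a covariate was chosen after the data were seen; the other alternatives were planned. The 31 probe sets past limma (16 higher, 15 lower) became 47 (25 higher) with quantile normalization and 61 (29 higher, 32 lower) with a robust fit, both with 30 or more of the 31 shared, and 3 (0 higher, 3 lower; 1060 higher at an unadjusted p of 0.05) without an intensity trend; the cause was not tested. A filter at the 60th percentile, which tests fewer probe sets, gave 48 (24 higher, 24 lower). Array weights gave 3466 (1605 higher, 1861 lower), with 46h replicate 1 and 54h replicate C weighted at 2.86 and 4.26 and the others at 0.372 to 0.630. These weights were estimated from the same arrays, and the fit then rests mostly on those 2 arrays, so its p-values may be too small. By construction an adjusted p of 0.1 gave 107 (48 higher, 59 lower) and a 1.5-fold minimum left 22 (9 lower). Leaving out 1 array, which shrinks the sample, gave 2 to 66 (0 to 44 higher, 2 to 34 lower): 2 without 46h replicate 1 or 54h replicate C (0 higher in each; 705 and 662 higher at an unadjusted p of 0.05), 18 without 46h replicate B, 30 without 46h replicate C (7 lower), 66 without 54h replicate 1 and 61 without 54h replicate B; why single arrays matter this much was not tested. With the liver covariate limma gave 0 probe sets (0 higher, 0 lower; 4557 at an unadjusted p of 0.05) and 0 lists (5 at an unadjusted p of 0.05). That signal correlated with the time point at 0.849 over the arrays, and the median SE went from 0.12 to 0.21. With the folds left as they were, the larger SE was enough to end every call (0 probe sets past limma's adjusted p), and 13 of the 31 folds also shrank: Sbsn went from -1.16 ± 0.06 to -1.15 ± 0.12 SE and Hsd17b7 from 1.17 ± 0.14 to 0.68 ± 0.18 SE, while Idi1 grew from 0.53 ± 0.07 to 0.67 ± 0.11 SE, and all 31 probe sets kept their direction. The cholesterol synthesis list turned from 0.27 to -0.15 under it, which did not pass. Of the 7 lists past camera, 4 to 6 passed with an array left out (4 without 46h replicate C, where medulla, adipose and immune genes did not pass, with medians of -0.07, 0.10 and -0.09). Without 54h replicate 1 a total of 8 lists passed, 6 of the 7 and also heat shock (median 0.03) and stroma (-0.10), while adipose genes did not (-0.02). Erythroid genes passed without a filter (0.09) and cell cycle genes with one at the 60th percentile (0.10). Of the 7 lists past camera, 6 passed with that stricter filter, 6 with quantile normalization and 5 with camera on ranks. Of all lists 0 passed with an estimated correlation (1, interferon, at an unadjusted p of 0.05) or fry on balance (3, liver, skeletal muscle and interferon, at an unadjusted p of 0.05), and 12 with fry in either direction. The estimated correlations of the liver, immediate early and cholesterol lists, 0.659, 0.387 and 0.703, exceed the preset 0.01. That is not the whole account, since skeletal muscle genes, with an estimated correlation of -0.053, also went from camera p = 0.0432 to 0.107. The cause was not tested, for camera or for fry on balance. Over all alternatives the adjusted p ran from 3.46e-12 to 0.616 for liver, 9.92e-18 to 0.753 for immediate early, 3.53e-20 to 0.861 for cholesterol and 5.90e-09 to 0.433 for interferon genes, and these 4 lists passed in each of the 6 leave-outs. The replicate block gave 45 probe sets, 22 of them among the 31, and 5 lists. Deviations of samples of the same letter correlated at r of -0.06, -0.41 and -0.49, and of different letters at -0.04 to 0.46. This gives no sign of pairing by letter. The highest r joined different letters, 0.46 for 46h replicate B with 54h replicate C and 0.38 for 46h replicate C with 54h replicate B. Correlations between arrays spanned nearly the same range within a time point as between time points. Whether letters or these crossed pairs mark shared batches stays open. Of genes named one by one, 0 that passed reversed; uncalled genes were not followed for sign. Named genes that passed only with an array left out or with another setting include Fos, Junb, Hspa1a, Hspa1b, Cyp51, Ttr, Apoa1, Mgst2 and Abcb1b without 54h replicate 1, Dusp1 and Dsg2 without 46h replicate C, and Eprs, Mgst2 and Abcb1b without 54h replicate B. Offsets, no filter and median centring gave 27 to 31 probe sets.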

Other observations

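The tests of 54h replicate 1, of the correlations of the immediate early genes, of the liver signal as a covariate for cholesterol genes and of other probe sets on 46h replicate C were chosen after the results they bear on were seen. The 4 further gene lists were also prompted by results already seen, though what each explanation predicts was written before they were tested.

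Further genes passed limma at a probe set other than their brightest; they fall outside the rule for named genes and were chosen after their values were seen. Masp1, a serine protease of the lectin pathway of complement, fell at 2 of its 3 measured probe sets, from 654 ± 95.1 to 263 ± 35.9 units and from 592 ± 63.6 to 262 ± 38.5 (SD, n = 3 each; limma adjusted p = 0.0288 for both), while the brightest had a log2 change of -0.10 ± 0.08 SE. Eprs rose at 2 probe sets with log2 changes of 0.86 ± 0.10 SE and 0.93 ± 0.12 SE. The 14-3-3 genes Ywhaz and Ywhae rose at 1 of 7 and 1 of 4 probe sets, by 0.65 and 0.48, against 0.15 and 0.01 at their brightest. Mgll, the monoacylglycerol lipase, fell at 1 probe set (-0.42 ± 0.06 SE), and its other 3 ranged from -0.34 to -0.15. Scd1, a fatty acid desaturase, rose at a dimmer probe set (0.79 ± 0.11 SE) and had 0.06 at the brightest, which read 12674 units at 46 h. The immunoglobulin A heavy chain gene Igha rose at 1 of 3 probe sets (0.73 ± 0.10 SE), the others having 0.72 and 0.30. All 4 Ttr probe sets had log2 changes between 1.11 and 1.46, and 1 passed.

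Some of these genes belong to groups that were not on the lists, and the hypothesis that each group moved together was tested on its other members, over 4 lists. The cytosolic aminoacyl-tRNA synthetases without Eprs had a median log2 change of 0.0676, with 15 of 20 higher (camera p = 0.00139, adjusted 0.00279; p = 0.268, adjusted 0.394, with an estimated correlation), so a joint rise with Eprs may be there but stays open. Amino acid synthesis genes without Psat1 had a median of 0.0323, with 8 of 13 higher (limma camera adjusted p = 0.187), which leaves it open whether they rose. Snhg1, Zfas1 and Snhg16 host snoRNAs, and 16 other host genes had a median of -0.0827, with 12 lower (limma camera adjusted p = 0.187), which did not pass. None of the members of these lists passed limma over all probe sets (0, with 5, 1 and 6 at an unadjusted p of 0.05).

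Liver genes were higher at 54 h, and a candidate explanation is liver tissue carried along in the dissection. A second list of liver genes had a median log2 change of 0.254, with 14 of 18 higher (camera p = 9.87e-06; p = 0.00876, adjusted 0.0350, with an estimated correlation), as carried tissue would give; Apoh had 0.79 and Serpinc1 0.92, but Apoc1 had -0.52, Hp 0.12, and Tat and Cyp7a1 of the first list had lower means at 54 h. Alb already read 2177 units at 46 h, so its probe set had signal at both times, and Tat is also on the glucocorticoid list. A response of adrenal cells themselves at 54 h was not tested and stays open. Whether carried liver could also account for the rise of cholesterol synthesis genes cannot be told apart: with the liver signal as a covariate their median turned from 0.27 to -0.153 and did not pass (limma camera adjusted p = 0.861, the highest of a range from 3.53e-20 over the alternatives), but that signal correlated with the time point at 0.849, so both can hardly be separated, and the levels of these genes in liver were not measured here.

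The immediate early and cholesterol synthesis lists stood highest on 54h replicates B and C. On 54h replicate 1 the list medians lay 0.0542 and -0.0300 from the 46 h mean, within the range of the 46 h arrays. For cholesterol genes the list mean, 0.0321, lay within that range too, with 5 of 19 genes, Hsd17b7 and Idi1 among them, above all 46 h arrays. For immediate early genes the mean, 0.133, lay above the highest of the 46 h arrays, 0.109, with 7 of 21 genes, Fos, Junb, Crem and Dusp1 among them, above all 46 h arrays, so it stays open whether B and C alone carry that rise. On B and C 18 and 18 of the immediate early and 18 and 16 of the cholesterol genes were above all 46 h arrays. A stress response before dissection may raise immediate early genes with inducible heat shock genes. After removal of the time point means both correlated over the 6 arrays (r = 0.945, exact permutation p = 0.0833; rho = 0.829, exact permutation p = 0.139), which did not pass, and r was 0.536 without 54h replicates 1 and B. Of 21 other lists only cholesterol synthesis gave a higher r (0.983), so a correlation this high was not unique to heat shock genes. The heat shock genes used were 5 chosen from a list with 20 measured. Setting them against lists without such a choice cannot show how rare this correlation is. Steroidogenesis and liver genes gave 0.909 and 0.777, and the lowest, cell cycle, gave -0.840. Since the exact permutation p did not pass, a stress response stays open, as does the time point itself, which the design names and which was not tested. 54h replicate 1 also stood apart in the 18S controls (2395 units at the 3′ end, against 1143 to 1751 on the other arrays, and 584 at the 5′ end, against 157 to 231). With 1 such array, whether its RNA or labelling bears on these lists stays open too. Both 18S controls were also higher on every 54 h array than on any 46 h array. A technical difference between the time points thus cannot be told apart from time.

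On 46h replicate C, 190 probe sets read at least 0.5 below every other array on the log2 scale, against 10 to 78 on the other 5, and this array lay farthest out on the first principal component (32.1, against -19.7 to 13.8 on the others), which held 37.0% of the variance. Other probe sets of the same genes did not follow: their median deviation was 0.07, near the 0.06 of all probe sets, against -0.98 for the affected ones, a ratio of -0.0690, in 71 affected probe sets with another to compare. An artefact of single probe sets is therefore a candidate explanation for this deviation. No biological explanation was tested.

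With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. The real split gave 31 probe sets and was 1 of 10 with as many, the highest other split giving 2. For lists the real split gave 7 and the highest other 8, from 46h replicates 1 and C with 54h replicate 1 against the rest; 3 of the 10 splits gave as many.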
